A study of Mus musculus with 11 samples.

How the data were processed

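miR levels were measured in total RNA from the whole aorta of 11 female apoE-/- mice (4 control, 4 after 3 months and 3 after 10 months of high fat diet), 1 mouse per array. RNA was extracted with the mirVana kit per the labels, and the design text states that RNA with an integrity number over 8 was used. The instrument, reagents, preamplification and software are not given in the sources used here.

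The authors deposited a non-normalized table of threshold cycles, a log2 scale read backwards on which 1 cycle later stands for about 2 times less template, and on which 40 stands for a well with no amplification, judging from the values. It holds 530 rows in 2 assay blocks: 335 and 182 miR assays and 13 wells of small-RNA or plant control assays. The second deposited table, on the same log2 scale, has 519 rows covering the same 517 miRs. In all 11 samples its values equal, up to rounding, the cycle number minus the mean of snoRNA202 (averaged over 2 wells) and snoRNA429, with wells at 40 kept as values. This was found by setting the 2 deposited data sets side by side, and no header or label states this step.

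The value used was minus the cycle number. Wells at 35 cycles or later, or with no amplification, counted as not detected and were set to 35. Each array was centred on the mean of the 285 miRs detected in all 11 samples (197 and 88 per block). The 353 miRs (235 and 118 per block) detected in at least 3 samples of at least 1 group were tested, and 100 miR assays were detected in no sample. Folds assume a doubling per cycle, which was not checked here. The depth of a PCR assay is its cycle number, and its precision is limited by the number of mice: the median standard error of a log2 fold was 0.46 at 3 months and 0.49 at 10 months against control.

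All 3 groups entered 1 model (lmFit and eBayes of limma 3.58.1 in R 4.3.3), which gave 8 residual degrees of freedom and a prior of 2.11 degrees of freedom with an SD of 0.61. Its tests are two-sided, and a miR was called at a Benjamini-Hochberg adjusted p under 0.05 over the 353 miRs. The 18 miR lists, fixed from general knowledge, were smooth muscle, muscle-specific, smooth muscle phenotype switching, leukocyte, macrophage activation, erythroid, endothelial, fibroblast and matrix, adipose and liver, neural, epithelial, lipid metabolism, ageing and senescence, the Dlk1-Dio3 imprinted cluster, the miR-17 cluster and its paralogs, let-7, miR-30 and embryonic stem cell. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Camera compares a list with the other miRs, whereas fry does not. The mean of each list per mouse, the number of miRs detected and the control assays were compared by exact two-sided permutation tests. Lists share members, so their results are not independent.

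The design, the lists, the alternatives and the rule for named miRs were fixed before the data were examined. The rule takes, for each comparison, the 12 largest rises and the 12 largest falls among called miRs detected in every sample of at least 1 of the groups compared. Where fewer than 5 pass it adds the 5 with the smallest unadjusted p. It then adds up to 4 members of each list with the smallest unadjusted p and 27 fixed miRs. Of these fixed miRs, 26 had an assay that was tested. Not every miR that the rule picks is given a value below, so the rule was not followed in full. Assay names were matched to the gene table of assembly GRCm38.p6 for neighbourhood only: 446 of 517 assays matched 1 gene, 57 several and 14 none. The sources used here name no build, so no coordinates are given.

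The test was tried on simulated data with 353 miRs and 20 simulations per comparison. Of miRs lowered by 2 on the log2 scale it called 68.1% at 3 months against control, 57.6% at 10 months against control and 62.0% between 10 and 3 months, and of those lowered by 1 it called 20.2%, 14.6% and 12.8%. Of all simulated calls 3.45%, 3.17% and 3.96% were false. The simulated miRs varied independently of each other and 100 of 353 were changed. These shares therefore do not describe measured miRs that move together.

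The alternatives were the array median, small-RNA control assays (snoRNA135, snoRNA202, snoRNA429 and U6), quantile normalization, no normalization, each assay block centred by itself, the deposited normalized values, undetected wells left missing, a limit of 32 cycles, only miRs detected in every sample, no filter, a fit of only the 2 groups compared, the replicate number as a block, a variance trend with robust variances, array weights, and each mouse left out in turn. A common floor after centring, snoRNA202 and snoRNA429 as reference with the 35-cycle limit, and the Dlk1-Dio3 list taken from the gene table were chosen after seeing the data. The erythroid and embryonic stem cell lists had too few tested members for a list test.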

Results

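Mature microRNAs (miRs) were measured by PCR in the whole aorta of 11 female apoE-/- mice, a strain that lacks apolipoprotein E and is prone to atherosclerosis. The labels put 4 mice on a normal diet (control, described as free of atherosclerosis). Another 4 mice were taken after 3 months and 3 mice after 10 months on a high fat diet, and their aortas are described as atherosclerotic. The diet held crude fat at 21%, casein at 19.5% and cholesterol at 0.15%. Each sample is a separate mouse per the labels. The design text states 4 biological replicates per group, whereas 3 samples are given for 10 months. The labels give an age of 6 to 8 weeks in all groups without saying whether this is the age at the start or at collection. How long the controls were kept is not stated either. Time on the diet and age therefore cannot be told apart in any of the 3 comparisons. The treatment label of the 10-month mice reads 3 months, whereas their titles and the design text read 10 months, and the titles were followed.

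Each sample held 517 miR assays, of which 322 to 380 were detected (below 35 cycles). The number detected was 353.2 ± 21.0 (SD, n = 4) in control aortas, 342.2 ± 6.85 (SD, n = 4) after 3 months and 348.7 ± 24.1 (SD, n = 3) after 10 months. These counts did not differ beyond the spread between mice. The exact two-sided permutation p was 0.429 for 3 months against control, 0.8 for 10 months against control and 0.6 for 10 against 3 months. The mean cycle number of the 285 miRs detected in all 11 samples ran from 23.2 to 26.9 and was latest in replicate 2 of the 10-month group, with exact two-sided permutation p of 0.771 or more between groups. With 4 mice against 4, or 3 against 4, the smallest p that an exact permutation test can give is 0.0286. Levels below are log2 values relative to the mean of those 285 miRs on the same array, and 353 miRs were tested.

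The comparison of 10 months of high fat diet with the normal diet asks which aortic miRs differ late in the disease. The Dlk1-Dio3 interval is an imprinted region whose miRs are made from the maternal chromosome. Of the 38 tested miRs of its list, 13 fell and 36 had a negative fold. miR-376c had the smallest p, at 1.30 ± 0.29 (SD, n = 4) in control aortas and -0.71 ± 0.10 (SD, n = 3) after 10 months, a 4.02-fold lower level (log2 fold -2.01, SE 0.25, limma adjusted p = 0.0034). miR-127, which lies antisense to the imprinted gene Rtl1, fell from 2.95 ± 0.28 (SD, n = 4) to 1.26 ± 0.72 (SD, n = 3), 3.21-fold lower (limma adjusted p = 0.0489). In the other direction, miR-21*, the passenger strand of miR-21, rose 3.05-fold (log2 fold 1.61, SE 0.37, limma adjusted p = 0.0475). The fold of miR-21 itself is not given here. Likewise higher, miR-193 rose 3.16-fold (log2 fold 1.66, SE 0.41, limma adjusted p = 0.0489).

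In all, limma called 16 of 353 miRs, of which 3 rose and 13 fell, and all 13 that fell lie in the Dlk1-Dio3 interval. With the array median in place of the mean as the centre, 16 were also called, split into 8 that rose and 8 that fell. Another split of the same mice gave 18 calls, of which 1 lies in the Dlk1-Dio3 interval. At an unadjusted p under 0.05 the counts were 27 higher and 33 lower. In 56 miRs (15.9%) the 3 mice and the 4 controls did not overlap, against 5.71% by chance. All 16 called miRs were among these, so each was lower, or higher, in 3 of 3 mice than in every control. Beside miR-376c and miR-127, the miRs that fell were miR-376a* (log2 fold -3.05, SE 0.66, detected in 2 of 3 mice), miR-376b (-2.30, SE 0.55), miR-411* (-2.16, SE 0.39), miR-337-3p (-1.94, SE 0.39), and miR-485* (-1.77, SE 0.32). They also included miR-379 (-1.76, SE 0.43), miR-376b* (-1.75, SE 0.37), miR-495 (-1.70, SE 0.32), miR-494 (-1.57, SE 0.29) and miR-337-5p (-1.56, SE 0.30), with limma adjusted p from 0.0226 to 0.0489. miR-434-3p (-1.28, SE 0.31, limma adjusted p = 0.0489) completes the 13 and is named after its values were seen. The third miR that rose was miR-129-5p, a miR enriched in brain (log2 fold 6.06, SE 1.20, limma adjusted p = 0.0246). It was detected in 3 of 3 mice but only 1 of 4 controls, so its fold depends on the value given to undetected wells.

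**Figure D1:**
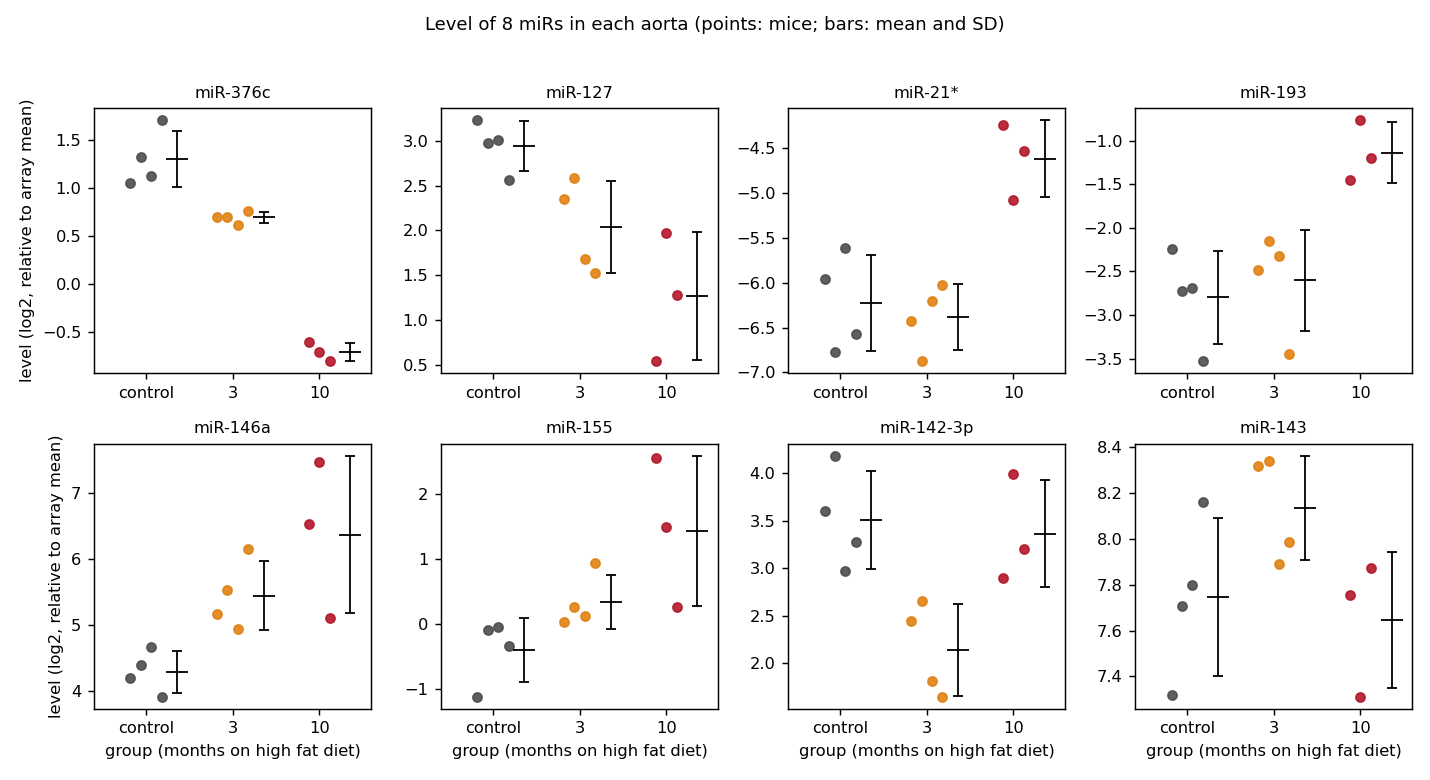
Level of 8 miRs in each aorta (vertical axes, log2 relative to the array mean) by group (control, 3 and 10 months of high fat diet), with points for single mice and bars for the mean and SD. miR-376c lies between 1.30 in controls and -0.71 after 10 months on average, with no overlap between groups, whereas miR-143 averages 7.75 in controls and 7.65 after 10 months.

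Of the 58 assays of the Dlk1-Dio3 list, 38 were tested, and at 10 months 36 of 38 had a negative fold (13 fell over all miRs, 21 fell when adjusted over the list alone). The median log2 fold was -1.44 (camera adjusted p = 3.82e-21), and this was the only list past the threshold with an estimated correlation (adjusted p = 0.000239). fry, which asks whether members move one way on balance, gave an adjusted p of 2.0e-05. Per mouse, the mean of the list was -2.77 ± 0.16 (SD, n = 4) in controls and -4.19 ± 0.12 (SD, n = 3) after 10 months, 2.68-fold lower in 3 of 3 mice. The exact two-sided permutation p was 0.0286, the smallest possible, and 0.152 after Benjamini-Hochberg adjustment over the lists.

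**Figure D2:**
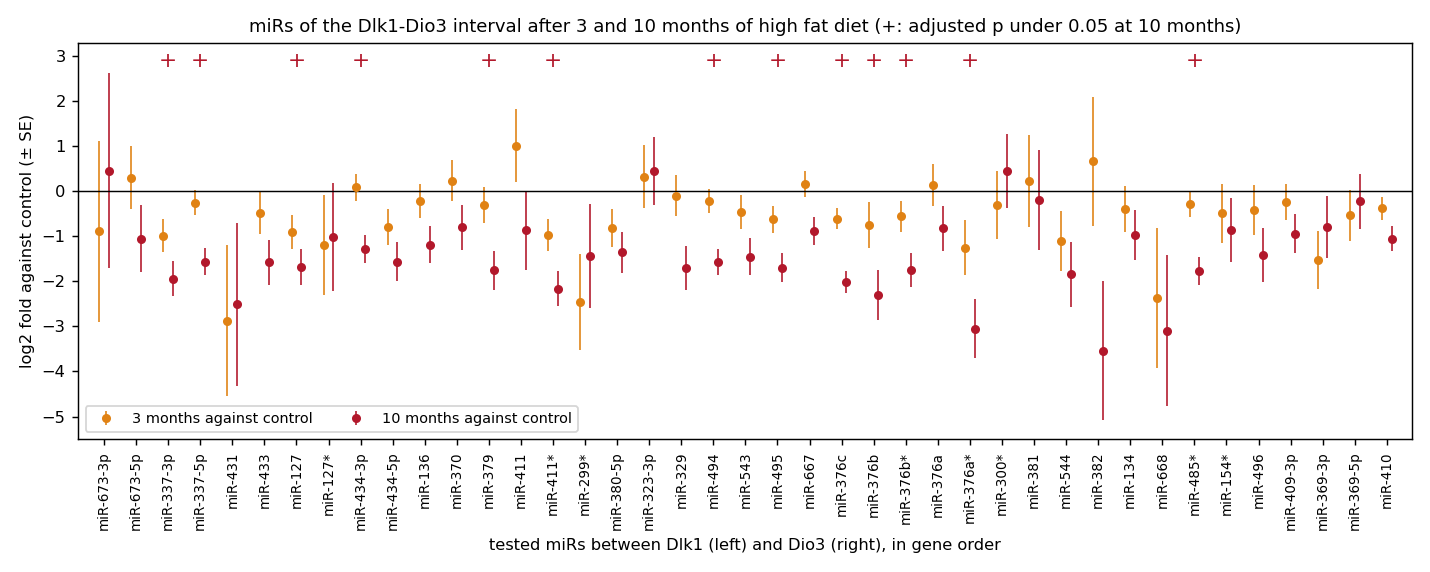
log2 fold against control (vertical axis, points with SE bars) of the 41 tested miRs whose genes lie between Dlk1 and Dio3, in gene order (horizontal axis), after 3 months (orange) and 10 months (red) of high fat diet; a plus marks an adjusted p under 0.05 at 10 months. The 13 marked miRs are spread along the interval from miR-337-3p to miR-485*.

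The macrophage activation list, miRs induced in macrophages by inflammatory ligands, was higher at 10 months (median log2 fold 1.13 over 12 miRs, camera adjusted p = 0.000507, but adjusted p = 0.186 with an estimated correlation). Of its members 1 rose (miR-21*), 0 fell and 11 did not pass limma over all miRs, and 6 rose when adjusted over the list alone. The examples that missed the threshold over all miRs include miR-146a, a feedback inhibitor of NF-kB signalling (log2 fold 2.08, SE 0.52, limma adjusted p = 0.0533), miR-146b (1.86, SE 0.52) and miR-155, an inflammatory miR of immune cells (1.83, SE 0.52, limma adjusted p = 0.0738). Per mouse, the list mean was 0.92 ± 0.24 (SD, n = 4) in controls and 2.03 ± 0.51 (SD, n = 3) after 10 months, higher in 3 of 3 mice. The exact two-sided permutation p was 0.0286 (0.152 after adjustment over the lists) and the fry adjusted p was 0.0224. The ageing and senescence list, miRs reported to rise in aged vascular cells, had a median of 1.08 over 10 miRs (camera adjusted p = 0.00332, adjusted p = 0.186 with an estimated correlation, fry adjusted p = 0.0173). Of its members 0 rose, 0 fell and 10 did not pass limma over all miRs, and 5 rose when adjusted over the list alone. Examples are miR-34b-3p (1.65, SE 0.48), miR-34c* (1.75, SE 0.58) and miR-34a, a target of p53 (1.30, SE 0.47, limma adjusted p = 0.162), and miR-146a stands in this list too.

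The leukocyte list, miRs enriched in blood cells, was higher at the preset correlation (median 0.75 over 12 miRs, camera adjusted p = 0.0421, adjusted p = 0.344 with an estimated correlation, fry adjusted p = 0.104). Of its members 0 rose, 0 fell and 12 did not pass limma, with 3 higher when adjusted over the list alone, and miR-146a, miR-155 and miR-147 are also in the macrophage activation list. Among the blood-cell miRs outside that list, log2 folds were 1.49 for miR-150, 0.66 for miR-142-5p, 0.62 for miR-223 and -0.14 for miR-142-3p, none past the threshold. Over the whole leukocyte list the mean log2 fold was 0.91, with 10 members positive and 2 negative. The list mean of replicate 3 of the 10-month group (-0.56) lay among the controls (-0.67 ± 0.25, SD, n = 4).

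Lists of the vessel wall and of neighbouring tissue did not pass camera. The mixed form of fry asks whether members change in either direction. It gave an adjusted p of 0.00813 for smooth muscle phenotype switching and 0.0393 for the neural list. The next smallest among these lists was 0.126, for fibroblast and matrix. The smooth muscle list (the miR-143 and miR-145 cluster, contractile smooth muscle) had a median log2 fold of -0.10 over 3 miRs, with miR-143 at -0.10 and miR-145 at -0.14 (camera adjusted p = 0.921). The endothelial list had a median of 0.20 over 8 miRs, with miR-126-3p at 1.03 (SE 0.36, limma adjusted p = 0.139). The smooth muscle phenotype switching list had a median of 0.27 over 12 miRs. The medians were 0.31 over 9 for fibroblast and matrix, 0.49 over 7 for adipose and liver, 0.11 over 8 for epithelial, 0.19 over 11 for the miR-17 cluster and its paralogs and 0.36 over 5 for the miR-30 family. The neural list had a median of 0.12 over 9 miRs, of which miR-129-5p rose and miR-129-3p was at 3.61 (SE 0.98, limma adjusted p = 0.0715). In the muscle-specific list miR-1, a striated muscle miR, was at -1.87 (SE 0.57, limma adjusted p = 0.0961). Mean, median and camera direction differed in sign for this list (median 0.0049, mean -0.39, direction down), lipid metabolism (median 0.13, mean -0.01, down) and let-7 (median -0.10, mean 0.03, down). Camera adjusted p ranged from 0.151 to 0.921 over these 12 lists. The erythroid list and the embryonic stem cell list had 2 tested members each and were not tested as lists. In the first, miR-451 was at -0.42 and miR-486 at 1.66, detected in 2 of 3 mice and 2 of 4 controls. In the second, miR-292-3p and miR-294 were detected in 0 of 3 mice (3 and 1 of 4 controls), so their folds reflect the limit of detection.

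**Figure D3:**
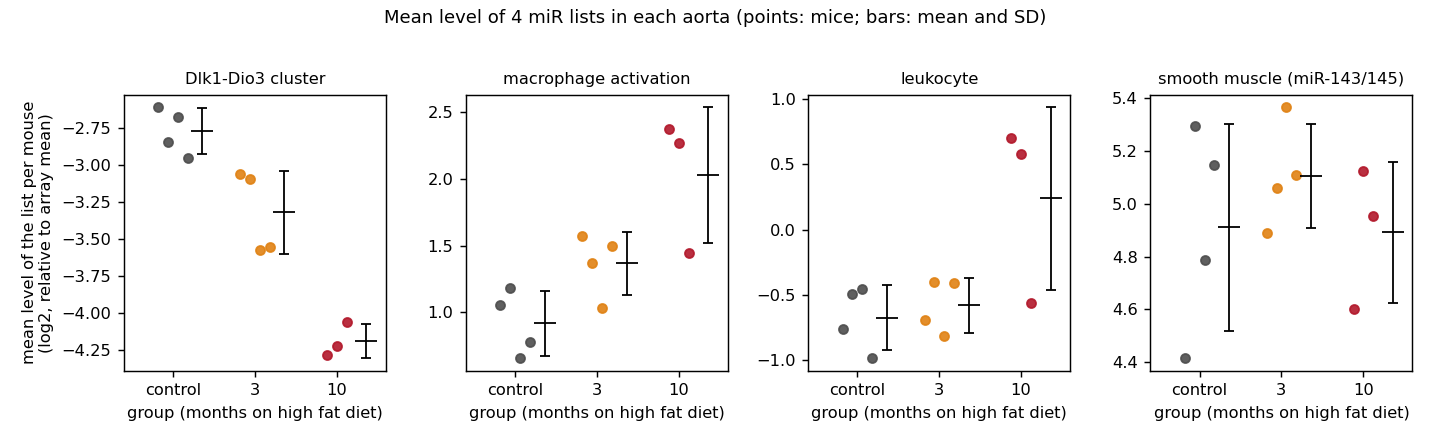
Mean level of 4 miR lists in each aorta (vertical axes, log2 relative to the array mean) by group, with points for single mice and bars for the mean and SD. The Dlk1-Dio3 means fall from -2.77 in controls to -3.32 after 3 months and -4.19 after 10 months without overlap, and the smooth muscle means overlap between all groups.

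The number of miRs called at 10 months moved with the design and the reference, while the folds kept their sign. miR-376c ran from -2.37 to -1.77 and miR-494 from -1.93 to -1.32 over 27 alternatives. limma called 0 miRs when only these 2 groups entered the fit (52 at an unadjusted p under 0.05, same folds, smallest limma adjusted p = 0.0629), with no normalization (14), with the small-RNA control assays as reference (26) and with the deposited normalized values (39). Leaving out 1 mouse left 1 call without control replicate 2, 2 without control replicate 4 or 10-month replicate 1, 3 without control replicate 1, 8 without 3-month replicate 1 or 3, and 10 without control replicate 3, 3-month replicate 2 or 10-month replicate 2.

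The comparison of 3 months of high fat diet with the normal diet asks which miRs differ earlier. The Dlk1-Dio3 list was lower, with a per-mouse mean of -3.32 ± 0.28 (SD, n = 4) against -2.77 ± 0.16 (SD, n = 4) in controls, 1.47-fold lower in 4 of 4 mice. The exact two-sided permutation p was 0.0286, the smallest possible, and 0.457 after adjustment over the lists. miR-376c was at 0.69 ± 0.06 (SD, n = 4) against 1.30 ± 0.29 (SD, n = 4), a log2 fold of -0.61 with no overlap between groups. miR-142-3p, a miR of blood-lineage cells, was at 2.14 ± 0.49 (SD, n = 4) against 3.51 ± 0.52 (SD, n = 4), also with no overlap. miR-125a-3p had the smallest p, with a log2 fold of 1.11 (SE 0.25, limma adjusted p = 0.320).

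No single miR passed: limma called 0 of 353, with 10 higher and 20 lower at an unadjusted p under 0.05. Groups did not overlap in 19 miRs (5.38%), against 2.86% by chance. After miR-125a-3p, the smallest p belonged to miR-135a (log2 fold -2.02, SE 0.49), miR-684 (-3.28, SE 0.83, detected in 0 of 4 mice and 3 of 4 controls), miR-129-5p (4.07, SE 1.11) and miR-142-3p (-1.37, SE 0.38), with limma adjusted p between 0.320 and 0.339. miR-146a was at 1.16 (SE 0.48), miR-146b at 1.01 (SE 0.48), miR-155 at 0.73 (SE 0.48) and miR-150 at 0.46 (SE 0.64), none past the threshold.

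In the Dlk1-Dio3 list 29 of 38 members had a negative fold, 0 passed over all miRs and 0 when adjusted over the list alone. The median was -0.47 (camera adjusted p = 0.000982, adjusted p = 0.111 with an estimated correlation, fry adjusted p = 0.0282). Examples were miR-337-3p at -0.98 (SE 0.37), miR-411* at -0.97 (SE 0.36) and miR-127 at -0.91 (SE 0.37). The macrophage activation list (median 0.49 over 12 miRs) and the miR-30 family (median 0.49 over 5 miRs, with miR-30e at 0.70, SE 0.26) were higher relative to the other miRs, each with camera adjusted p = 0.0154 and adjusted p = 0.608 with an estimated correlation. In both, 0 members passed over all miRs or when adjusted over the list alone. With the control assays as reference their medians were -0.26 and that of all miRs -0.81. Both lists thus still lay above the median of all miRs, but neither passed camera there. The other 13 lists tested had camera adjusted p from 0.106 to 0.942, among them the leukocyte list (median 0.20, direction up by camera and down by fry), smooth muscle (0.38), endothelial (0.08), ageing and senescence (0.10) and let-7 (0.47). Median, mean and test differed in sign for fibroblast and matrix (median -0.08, mean 0.08, direction up) and lipid metabolism (median 0.03, mean 0.03, direction down).

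Between 10 and 3 months of the diet, the Dlk1-Dio3 list was lower relative to the array mean, with a per-mouse mean 1.83-fold lower in 3 of 3 mice (-4.19 ± 0.12, SD, n = 3, against -3.32 ± 0.28, SD, n = 4). The exact two-sided permutation p was 0.0286, the smallest possible, and 0.274 after adjustment over the lists. Of its 38 members 31 were negative, 0 fell over all miRs and 11 fell when adjusted over the list alone. The median log2 fold was -0.99 (camera adjusted p = 4.90e-14, adjusted p = 0.00129 with an estimated correlation, fry adjusted p = 0.000424). The size of this step depends on the reference. The median was -0.09 with the small-RNA control assays, -0.41 with snoRNA202 and snoRNA429 and -0.48 with deposited normalized values. With the control assays the list was nearly as low at 3 months (-1.22) as at 10 months (-1.29) against control, and the median of all miRs between 10 and 3 months was 0.97. Relative to the median of all miRs, the list lay between -1.25 and -0.90 over the alternatives that kept every mouse. The leukocyte list was higher (median 0.89 over 12 miRs, camera adjusted p = 0.0207, adjusted p = 0.398 with an estimated correlation), with 0 members past the threshold over all miRs or when adjusted over the list alone. miR-142-3p was at 1.22 (SE 0.41), with a level of 3.37 ± 0.56 (SD, n = 3) at 10 months, and miR-155 at 1.09 (SE 0.52), neither past the threshold.

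limma called 0 of 353 miRs between 10 and 3 months, with 22 higher and 24 lower at an unadjusted p under 0.05, and 43 (12.2%) without overlap against 5.71% by chance. The smallest p belonged to miR-376c (log2 fold -1.40, SE 0.25, limma adjusted p = 0.0711), miR-21* (1.77, SE 0.37), miR-485* (-1.50, SE 0.32), miR-494 (-1.35, SE 0.29) and miR-337-5p (-1.31, SE 0.30). miR-1 was at -2.05 (SE 0.57, limma adjusted p = 0.161) and miR-34a at 1.22 (SE 0.47, limma adjusted p = 0.328). The ageing and senescence list (median 0.73, camera adjusted p = 0.0515), macrophage activation (0.72, camera adjusted p = 0.0763) and let-7 (-0.75, camera adjusted p = 0.0731) lay near the threshold, and the other 11 lists had camera adjusted p from 0.431 to 0.766. In lipid metabolism the median (0.06) and the mean (-0.03, direction down) differed in sign.

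The folds at 3 and at 10 months share the same 4 controls, which links them with no effect at all. Across the 353 miRs, which are not independent replicates, the folds had Pearson r = 0.33 and Spearman rho = 0.37, against a mean r of 0.44 (-0.32 to 0.89) in 2000 simulations of unchanged groups with shared controls. The covariance was 0.406 against a simulated 0.415, and with the controls split between the comparisons the mean r over 6 splits was 0.00. Of the 16 miRs called at 10 months, 14 had the same sign at 3 months and all 16 had a smaller fold there, which choosing them at 10 months favours. With the small-RNA control assays as reference 15 of 16 had a smaller fold at 3 months. miR-127 was then at -1.66 at 3 months and -1.53 at 10 months, and miR-337-3p at -1.74 and -1.78. This reference shifted all miRs, with a median of -0.81 at 3 months and 0.16 at 10 months. No miR was called in both comparisons, since limma called 0 at 3 months (30 at an unadjusted p under 0.05), and independent lists would share 0.

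The small-RNA control assays, relative to the same array mean, did not pass after adjustment. U6 was higher by 1.27 (log2) at 3 months than in controls (exact two-sided permutation p = 0.0286, 0.514 after adjustment over 18 comparisons) and by 0.39 at 10 months. snoRNA202 was at -0.43 at 10 months against control (exact two-sided permutation p = 0.0857) and snoRNA429 at -0.01. Between 10 and 3 months the differences were larger for snoRNA202, at -0.86 (exact two-sided permutation p = 0.0571, 0.514 after adjustment). In that comparison snoRNA135 was at -1.29 (exact two-sided permutation p = 0.143), U6 at -0.88 (0.343) and snoRNA429 at -0.30 (0.6). Y1 had the largest differences, -2.04 at 10 months against control and -2.37 between 10 and 3 months (exact two-sided permutation p = 0.629 and 0.486). Its well in the second block of 10-month replicate 2 was at 40 cycles and weighs heavily in both. U87 was at 0.25, -0.42 and -0.68 at 3 months, at 10 months and between them.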

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

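Except for the test of wells at 40 cycles against late samples and the counts over other splits of the mice, the tests of explanations below were chosen after the results were seen.

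In control aortas the level of miR-133a in replicate 3 (6.69) stood apart from the other controls (7.02 to 7.06). At 3 months, miR-376b* in replicate 2 (-1.32) stood apart from the others (-0.75 to -0.67). Among 138 groups of 4 mice examined in this way 2 stood apart, against 6.9 expected by chance. The leukocyte list differed between the effects of 10 and 3 months (median 0.89, camera adjusted p = 0.0207, adjusted p = 0.398 with an estimated correlation), and so did the Dlk1-Dio3 list (median -0.99, camera adjusted p = 4.90e-14, adjusted p = 0.00129 with an estimated correlation). The size of the latter depends on the reference, with medians of -0.09 with control assays, -0.41 with snoRNA202 and snoRNA429 and -0.48 with deposited normalized values. These references shifted all miRs, whose medians were then 0.97, 0.64 and 0.63. Relative to the median of all miRs, the list lay between -1.25 and -0.90 over the alternatives that kept every mouse. The plant assay ath-miR159a, which should not amplify from mouse RNA, gave 33.98 cycles in the second block of control replicate 1 and 40 in the other 21 of 22 wells.

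The lower Dlk1-Dio3 list at 10 months (per-mouse difference -1.42) was weighed first. Low template in 10-month replicate 2 is argued against by a difference of -1.40 without that mouse. The choice of reference is argued against by a list median of -1.20 or lower under 7 other normalizations. The camera p of the list bears little on the reference (largest adjusted p = 1.85e-17 at the preset correlation, adjusted p = 0.000239 with an estimated correlation by the planned analysis). Camera compares the list with the other miRs, and most of these references shift all miRs alike. Fewer vessel-wall cells per RNA is argued against by a smooth muscle list difference of -0.019 (95% interval -0.55 to 0.51) and a fibroblast and matrix difference of 0.21 (-0.09 to 0.52). Cells too few to move these lists were not tested. An effect of long feeding may explain the pattern, and so may the greater age these mice could have reached, since the design does not separate them and neither was tested.

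The higher macrophage activation list at 10 months (per-mouse difference 1.11) was weighed next. Low template in replicate 2 is argued against by a difference of 0.99 without that mouse. The reference is argued against by medians of 0.77 or higher under 7 other normalizations. Here too the camera p (largest adjusted p = 0.000788 at the preset correlation) bears little on the reference. The list itself did not pass with adjusted p = 0.186 with an estimated correlation. More leukocytes in the aorta was first tested on miR-142-3p, miR-142-5p and miR-223, whose mean differed by 0.38 (95% interval -0.22 to 0.98, exact two-sided permutation p = 0.257), an upper end below 1.11 that argued against leukocytes as the whole cause by the bound set for it. That set left out miR-150, which is abundant in lymphocytes, and after this result was seen it was added: the mean of 4 then differed by 0.65 (-0.08 to 1.39, exact two-sided permutation p = 0.143), an interval that holds both 0 and 1.11. At 3 months the 3 markers were at -0.51 (exact two-sided permutation p = 0.0286) and the 4 at -0.27 (exact two-sided permutation p = 0.257). The macrophage activation list was not firmly higher there (mean 0.45, camera adjusted p = 0.608 with an estimated correlation, 0 members called). With control assays its median was -0.26 and that of all miRs -0.81, so it still lay above the median of all miRs. The whole leukocyte list, which shares members with the macrophage activation list, differed by 0.91 at 10 months against control. Its exact two-sided permutation p was 0.0857. A larger leukocyte share at 10 months may contribute and stays open, as do activation of resident cells and age, which were not tested.

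Wells at 40 cycles were weighed last: 26 assays with a median below 27 cycles where detected held 107 such wells. Some of these assays were at 40 in most mice: miR-297c and miR-687 in 10 each, miR-483* in 9, and miR-23a, miR-199a-5p and miR-696 in 8 each. Their medians rest on the few wells that amplified, so they need not be abundant. Late samples could account for the wells at 40. Of these wells 26.2% lay in the 2 samples with the latest mean cycle number, against 18.2% under equal shares and a bound of 25.6%. The bound takes the wells as independent, and assays at 40 in most mice push the shares towards equal. The test therefore leaves late samples open. Per mouse, such wells numbered 5 to 13 in controls, 9 to 11 at 3 months and 6 to 15 at 10 months, so the totals overlapped between groups. A response of single assays to the diet may also contribute and stays open: 0 of the assays were at 40 in every mouse of a diet group and detected in every control, but only an all-or-none response could show this way. Of the 26 assays 9 had a single well at 40, and let-7b* was at 40 in 4 of 4 mice at 3 months and 1 of 4 controls. let-7f, miR-382, miR-429, miR-431 and miR-486 are among these assays, and single wells weigh heavily in their folds.

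Other splits of the same mice into groups of the same sizes did not exclude chance for the count of miRs at 10 months against control or for the counts of lists. At 10 months against control, 2 of 35 splits gave as many as 16 miRs, with 18 in the highest other split. That split set control replicates 1 and 2 and 10-month replicate 2 apart, and 1 of its 18 miRs lies in the Dlk1-Dio3 interval. At 3 months against control and between 10 and 3 months the real count was 0, which any split reaches, so the 35 of 35 splits with as many test nothing (1 and 2 in the highest other split). Lists past the threshold numbered 3, 4 and 2 in the order 3 months against control, 10 months against control and 10 against 3 months. As many were given by 10, 10 and 16 of 35 splits, and the highest others had 4, 5 and 7. At the preset correlation 31, 32 and 30 of the other splits put at least 1 list past the threshold. The Dlk1-Dio3 list passed in 7, 20 and 16 of them. Some of these splits keep most mice of a group together, so a real difference could make the list pass there too. They therefore cannot show how often the list passes by chance, and passing at the preset correlation is not read as support by itself. With an estimated correlation, no other split passed any list, against 0, 1 and 1 in the real ones, and the size of the Dlk1-Dio3 median was largest in the real split of each comparison (largest other 0.36, 1.15 and 0.92).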

How the results depend on the processing

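The common floor, snoRNA202 with snoRNA429 as reference and the gene-table Dlk1-Dio3 list were chosen after the data were seen; the other alternatives were planned. The Dlk1-Dio3 list stayed lower and, at the preset correlation, past the threshold in all 28 alternatives of each comparison, with medians of -1.22 to -0.33 at 3 months, -1.80 to -1.05 at 10 months and -1.29 (no normalization) to -0.09 (control assays) between them (largest adjusted p 0.0477, 2.75e-16 and 2.38e-08). Not all of these could move it: fitting only 2 groups, the variance trend and leaving out a mouse of the third group kept the median unchanged. A reference that shifts all miRs alike leaves the place of the list among the other miRs, which camera tests, much the same. Relative to the median of all miRs it lay at -0.44 to -0.36, -1.59 to -1.34 and -1.25 to -0.90 with every mouse kept. By the planned analysis its adjusted p = 0.111 at 3 months, 0.000239 at 10 months and 0.00129 between them with an estimated correlation. With control assays as reference the medians of the macrophage activation list and the miR-30 family at 3 months were -0.26. The median of all miRs was then -0.81, so both still lay above it. The difference in miRs detected at 10 months against control went from -4.58 to 8.75 without 10-month replicate 2.

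The 16 miRs called at 10 months against control became 0 with control assays as reference, no normalization, deposited normalized values, only the 2 groups compared, and snoRNA202 and snoRNA429 (by limma, with 14 to 52 at an unadjusted p under 0.05). They became 1 with no filter, 29 with only miRs detected in every sample and 25 with array weights, and ran from 1 to 12 when a mouse was left out. At 3 months, leaving out a mouse gave 0 to 1. Between 10 and 3 months the count of 0 became 4 with quantile normalization, 5 with each assay block centred separately, 1 with deposited normalized values, 1 with variance trend and robust variances, 10 with array weights and 6 with the common floor. The 3 lists past the threshold at 3 months became 1 with control assays, no normalization, deposited values, and snoRNA202 and snoRNA429 (1 to 4 with a mouse left out); the 4 lists at 10 months ran from 3 to 5. The 2 lists between 10 and 3 months became 4 with quantile normalization, separate blocks, missing wells, no filter and the replicate block, and 1 with no normalization, deposited values, a limit of 32 cycles, and snoRNA202 and snoRNA429 (1 to 5 with a mouse left out). The cause of these shifts was not tested.

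Same-numbered mice were not treated as pairs, since not every pair of deviations had a correlation over 0.1. That rule cannot dismiss an effect shared by mice of the same number. It was over 0.1 in 7 of 10 same-number pairs (mean 0.147, lowest -0.356) and in 5 of 30 pairs with different numbers (mean -0.049). The 2 means are linked, because deviations within a group sum to 0. With the replicate block 6 miRs were called at 10 months, of which 0 rose and 6 fell. The macrophage activation and ageing lists at 10 months were past the threshold at the preset correlation in 27 of 27 alternatives, and the leukocyte list in 14. By the planned analysis the first 2 had adjusted p = 0.186 with an estimated correlation, and the leukocyte list had adjusted p = 0.344 with an estimated correlation. miR-376c was past it in 22 of 27, miR-21* and miR-193 in 10 each. Over all alternatives, the 16 called miRs kept their side of the threshold in 212 instances and lost it in 218.

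The median log2 fold of all miRs shifted to -0.81, 0.16 and 0.97 (3 months, 10 months, 10 against 3) with control assays, -0.40, 0.20 and 0.63 with deposited values, -0.11, -0.35 and -0.24 with no normalization, and -0.41, 0.23 and 0.64 with snoRNA202 and snoRNA429. With median centring it was 0.25 at 10 months and 0.34 between 10 and 3 months. Late cycles in 10-month replicate 2 limit what could be detected in that group.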

Other observations

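All tests in this part were chosen after the results were seen.

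Neighbouring miR genes gave a finer picture of the Dlk1-Dio3 interval. When miRs whose genes lie within 50 kb of each other were grouped into 19 clusters of 116 tested miRs, 2 clusters of the interval were lower at 10 months than in controls: the one from miR-673-3p to miR-370, with 12 miRs and a median log2 fold of -1.42 (camera adjusted p = 2.55e-06, adjusted p = 0.00857 with an estimated correlation, 4 miRs called), and the one from miR-379 to miR-410, with 29 miRs and a median of -1.44 (camera adjusted p = 2.16e-14, adjusted p = 0.000745 with an estimated correlation, 9 miRs called). At 3 months the second had a median of -0.42 (camera adjusted p = 0.00712, adjusted p = 0.160 with an estimated correlation), and the first, at -0.63, did not pass (camera adjusted p = 0.152). Of 3 tested miRs of the interval outside the list, miR-544 was at -1.84, miR-409-3p at -0.94 and miR-300* at 0.45 at 10 months, none past the threshold.

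The miR-34b/c cluster, a target of p53, was higher at 10 months than in controls, with a median of 1.75 over 3 miRs (camera adjusted p = 0.0307, adjusted p = 0.347 with an estimated correlation). The cluster of miR-143 and miR-145, by contrast, had a median of -0.10.

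The deposited normalized values keep wells at 40 cycles as values, so that 95 assays at 40 in all 11 samples read 20.29 in 10-month replicate 2 and 22.60 to 24.58 in the other samples. These undetected assays give an apparent log2 fold of 0.58 at 10 months against control, and of -0.81 without that mouse. The values used here carry an offset of the same kind, since undetected wells were set to 35 before centring. Such wells read -8.08 in 10-month replicate 2 and -11.83 to -9.70 in the other samples. With a common floor after centring limma called 19 miRs at 10 months against control and 6 between 10 and 3 months.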
